A study of Schmidtea mediterranea with 24 samples.

How the data were processed

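RNA abundance was measured by sequencing in tails of asexual planarians (*Schmidtea mediterranea*, clonal line CIW4). Per the labels' protocols, animals were starved for 7 days, and the extracellular vesicles (EVs) came from tissue fragments collected 12 hours after amputation, enriched by differential centrifugation, polymer precipitation and size exclusion. Vesicles, or buffer in their place, were injected into tails together with a fluorescent dextran, and animals that held little dextran 1 hour later were discarded. That selection concerns injected animals, so comparisons with uninjected animals carry it along with the injection. Tails without about 10% at the posterior tip were collected 24 hours after injection, 5 fragments to a replicate, with 4 biological replicates in each of 3 groups. The sample titles give that time for injected tails only. Libraries were made from poly-A selected RNA, per the labels' protocols, and read as pairs of 150 bases in 2 sequencing runs.

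The authors deposited read counts per transcript for each run and for both runs together, as whole numbers with no normalization, with the transcript length in bases per the file headers. Per the submitters' processing notes and the series' design text, the tools were FastQC 0.11.5, BBDuk, Bowtie2 2.3.1, featureCounts from Subread 1.6.3 and edgeR 4.0.16. The version of BBDuk, the strand setting and the treatment of reads that map to several transcripts are not given in the sources used here. Counts of transcripts that share sequence, or that overlap on opposite strands, are therefore uncertain. The authors also deposited a table of their own 3 comparisons, which gives log2 fold changes and log2 mean CPM per the file headers. The same deposited table holds an F score and a p-value with its false discovery rate for each comparison, per the file headers. It lists 17755 transcripts, exactly those that reach 1 CPM in at least 4 of the 12 libraries of the deposited counts.

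The 24 sequencing samples are 12 libraries with 2 runs each. The runs were summed and each library was counted as 1 replicate. The sums equalled the authors' deposited counts for both runs together in all 344904 cells. No column belonged to another sample. Pairs of libraries were compared by the mean chi-square per transcript over transcripts with at least 50 counts. It was 1.50 to 1.95 between runs of 1 library and 4.33 to 18.5 between libraries of 1 group, so no library was treated as a repeat of another.

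The files name transcripts by identifier and pair none of them with a gene name. No genome or annotation was used here. The 28 lists of named genes fixed in advance could not be applied, and no list test was run. Transcripts are printed by identifier only, under a rule fixed before the data were examined. Per comparison, the rule takes the 2 largest rises and the 2 largest falls among transcripts with an adjusted p under 0.05, a mean log2 CPM of at least 0 and no overlap between the groups' libraries.

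Counts were analysed in R 4.3.3 with edgeR 4.0.16, using filterByExpr on the groups, TMM scaling and the quasi-likelihood F test in 1 model over all 12 libraries, with no covariate. The filter kept 21149 of 28742 transcripts, which held 99.9% of counts, and 221 transcripts had no count in any library. A transcript was called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold change. Standard errors (SE) of log2 fold changes were derived from the F statistic, and CPM values are scaled by TMM and given as mean ± SD. Where a group held very few counts, the ratio of summed counts is given with an exact 95% interval from the conditional binomial distribution, which covers counting error only. Comparisons that share libraries were set against 20 simulated data sets without any effect and against the product of list sizes over the number tested, and were repeated with the shared libraries divided.

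Library totals ran from 19621187 to 30903133 counts. The biological coefficient of variation was 7.62%. The test was checked on simulated data with the real totals and with means and spread estimated over all 12 libraries, drawn independently. In these data 200 of 21149 transcripts were changed in the EV-injected libraries. The test recovered 28% of them at 1.25-fold with 6 false calls and 52% at 1.5-fold with 6 false calls. At 2-fold it recovered 80% with 10 false calls. Recovery at the wider spread of the buffer-injected group, 9.16%, was not measured.

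The alternatives fixed in advance were DESeq2 size factors, DESeq2 1.42.0, limma-voom (limma 3.58.1), no count filter, the filter of 1 CPM in 4 libraries, a robust fit, only the 8 libraries compared, the replicate number as a block, each run alone, a minimum fold of 1.5, and each library left out. Added after seeing the data were thinning of every library to the smallest total and a covariate for the first axis of variation within groups. Figures were drawn with matplotlib 3.10.9.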

Results

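Planarians are flatworms that regrow lost tissue from stem cells spread through the body. The study looked for transcripts that respond to EVs, the membrane-bound particles that cells release, by injecting EVs from regenerating fragments into the tails of intact animals. RNA was measured 24 hours later in 4 EV-injected and 4 buffer-injected tail pools, and also in 4 uninjected tail pools. Each library held 19621187 to 30903133 counts. Mean totals were 23615960 in the EV-injected, 24852827.5 in the buffer-injected and 23931315 in the uninjected group.

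Injected tails stood apart from uninjected tails. The first principal component of the 1000 most variable transcripts held 41.5% of their variance. Its score was −19.6 ± 3.54 in uninjected, 10.2 ± 8.61 in buffer-injected and 9.44 ± 3.37 in EV-injected tails (SD, n = 4 each). Each injected group differed from the uninjected group (exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 allows, adjusted p = 0.0429 over 6 tests). The injected groups did not differ from each other on it (exact permutation p = 0.886, adjusted p = 0.886). The 10 most abundant transcripts of a library took 8.88% ± 0.0452 of counts in uninjected, 7.61% ± 0.128 in buffer-injected and 7.50% ± 0.146 in EV-injected tails, with the same exact p of 0.0286 for either injected group against the uninjected group. Spread between replicates was wider in the buffer-injected group, with a coefficient of variation of 9.16% against 6.32% in uninjected and 7.17% in EV-injected tails.

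**Figure D1:**
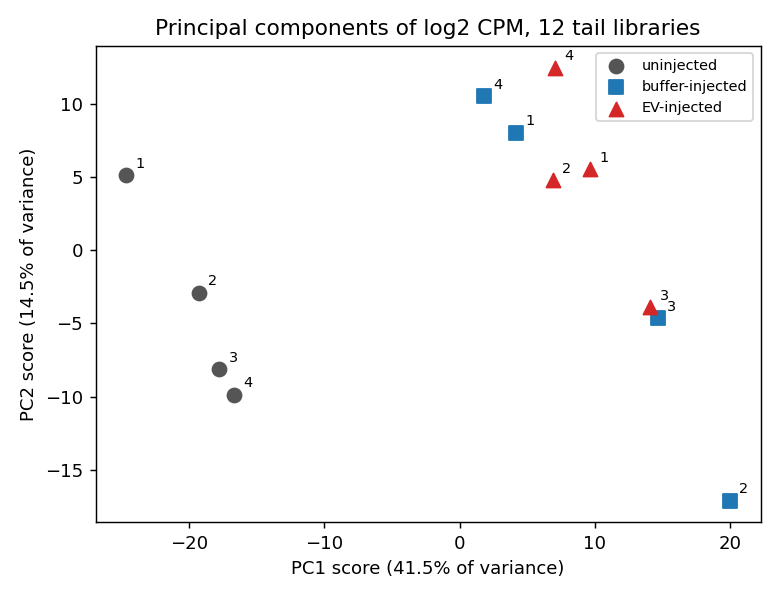
Scores of the 12 libraries on the first and second principal components of log2 CPM, over the 1000 most variable transcripts; each point is a library, marked by its group and replicate number. The uninjected libraries lie on the left and all injected libraries on the right, with buffer-injected replicate 2 at −17.1 on the second component.

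The comparison of buffer-injected with uninjected tails asks what the injection does without EVs. The largest rises were in transcripts close to absent from uninjected tails. dd_Smed_v6_10584_0_1 had 2 counts over the 4 uninjected libraries and 177 over the 4 buffer-injected ones, a ratio of 83.3 with a 95% counting interval of 22.7 to 693. dd_Smed_v6_36866_0_1 had 4 against 274 counts, a ratio of 64.5 with an interval of 24.9 to 238. The largest falls were in dd_Smed_v6_8938_0_1, from 10.1 ± 1.66 to 1.38 ± 1.31 CPM, and in dd_Smed_v6_21015_0_1, from 1.97 ± 0.340 to 0.429 ± 0.149 CPM (SD, n = 4 each). Their log2 fold changes were −2.93 ± 0.34 and −2.21 ± 0.28 (SE), with edgeR adjusted p of 5.8e-06 and 1.26e-05. For dd_Smed_v6_8938_0_1 the change was −3.74 without buffer-injected replicate 1, which had 3.25 CPM against 0.343 to 1.31 in the other buffer-injected libraries. For dd_Smed_v6_21015_0_1 it was −1.71 with run 1 alone and −3.33 with run 2 alone.

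In all, 4659 of 21149 tested transcripts were called in this comparison with edgeR, 2629 higher and 2030 lower after buffer injection. Most changes were small. The median size of a called change was 0.32 on the log2 scale, and 932 called transcripts changed by at least 1.5-fold, 502 up and 430 down. At 2-fold or more, 208 rose and 118 fell. These counts were 158 and 75 with a filter of 1 CPM in 4 libraries, and 159 and 91 with DESeq2. The rises were 159 without buffer-injected replicate 2 or buffer-injected replicate 3, and 254 without buffer-injected replicate 4. At 4-fold or more, 49 rose and 4 fell, but these counts depend on the libraries, the filter and the tool. They were 30 rises and 9 falls without buffer-injected replicate 2, 29 and 7 with limma-voom, 30 and 4 with a robust fit, and 85 and 21 without a filter. The falls were 7 without buffer-injected replicate 1, 11 without buffer-injected replicate 3, and 2 with DESeq2 or the filter of 1 CPM. The groups did not overlap for 4019 of the called transcripts, and over all tested transcripts this held for 23.8%, where chance gives 2.857%. The authors' deposited table calls 4694 transcripts, 2556 up and 2138 down, among 17755.

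The comparison of EV-injected with uninjected tails takes EVs and injection together, and the rule named the same 4 transcripts. dd_Smed_v6_10584_0_1 had 2 against 180 counts, a ratio of 88.0 with a 95% counting interval of 24.0 to 732. dd_Smed_v6_36866_0_1 had 4 against 220 counts, a ratio of 53.8 with an interval of 20.7 to 199. dd_Smed_v6_8938_0_1 fell to 0.835 ± 0.240 CPM and dd_Smed_v6_21015_0_1 to 0.485 ± 0.199 CPM (SD, n = 4 each). Their log2 fold changes were −3.57 ± 0.37 and −2.0 ± 0.27 (SE), with edgeR adjusted p of 1.2e-06 and 2.31e-05. None of these 4 transcripts was called between EV-injected and buffer-injected tails, where edgeR adjusted p ran from 0.701 for dd_Smed_v6_8938_0_1 to 0.969 for dd_Smed_v6_10584_0_1.

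**Figure D2:**
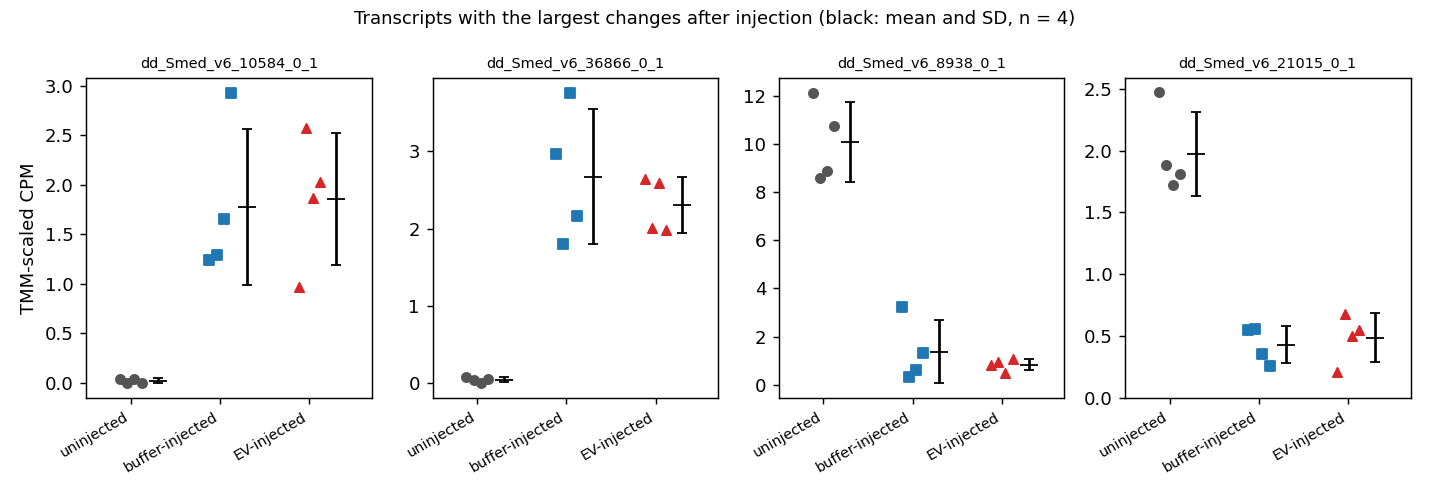
TMM-scaled CPM per library of the transcripts with the largest rises and falls after injection; points are libraries, and black marks are the mean and SD (n = 4) of the uninjected, buffer-injected and EV-injected groups. dd_Smed_v6_10584_0_1 and dd_Smed_v6_36866_0_1 are near 0 only in uninjected tails. dd_Smed_v6_8938_0_1 and dd_Smed_v6_21015_0_1 are lower in every injected library than in every uninjected one. The rule that named these transcripts required that injected and uninjected libraries not overlap.

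Here 5452 of 21149 transcripts were called with edgeR, 2935 higher and 2517 lower in EV-injected tails. The median called change was 0.33 on the log2 scale. At 1.5-fold or more 479 rose and 527 fell, and at 2-fold or more 154 rose and 147 fell, or 96 with a filter of 1 CPM in 4 libraries. At 4-fold or more 34 rose, and the number that fell, 10, was 2 with DESeq2 or that filter, 4 with run 2 alone and 41 without a filter. The groups did not overlap for 4665 of the called transcripts, and over all tested transcripts this held for 26.4%. The authors' deposited table calls 5499 transcripts, 2883 up and 2616 down. The count here exceeded that of buffer-injected tails by 793 transcripts. The difference was 274, 429, 48 and 118 without EV-injected replicates 1 to 4. Without buffer-injected replicates 1 to 4 it was 1204, 1354, 1571 and 1049. The group that lost a library had fewer calls each time, so smaller group size and single libraries cannot be told apart here. Of 70 ordered divisions of the 8 injected libraries, 4 gave a difference as large, the real one included.

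The responses to EV and to buffer injection were set side by side. A total of 3730 transcripts were called in both, 2086 higher and 1644 lower, and 0 went in opposite directions. Independent lists of these sizes would share 365 rises and 242 falls, and simulated data without effects shared 0, but called at most 3 and 2 transcripts in the comparisons. Simulated data with the injection effect and no EV effect shared 3988 to 4121 calls, out of longer buffer lists of 5168 to 5422 calls. With the uninjected libraries divided between the comparisons, 2199 to 2276 calls were shared. A further 1722 transcripts were called only with EVs and 929 only with buffer. A call in 1 comparison alone does not test a difference between EVs and buffer. The direct comparison does, and it called 6 of the 1722 and 5 of the 929. Across transcripts, which are not independent replicates, the log2 fold changes correlated at r = 0.826, against 0.507 in simulated data without effects and 0.885 to 0.891 with the injection effect and no EV effect. Their covariance was 0.105, against 0.0171 and 0.132 to 0.138. The real correlation and covariance lie below those with the injection effect. That simulated effect was taken from the observed means with their sampling error, and new error was drawn on top, which raises the simulated values. The gap is therefore no measure of a difference between the EV and buffer responses. Simulated libraries also vary independently, and how much each of these adds was not tested. With divided controls r was 0.515 to 0.547 and the covariance 0.0908 to 0.0938.

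**Figure D3:**
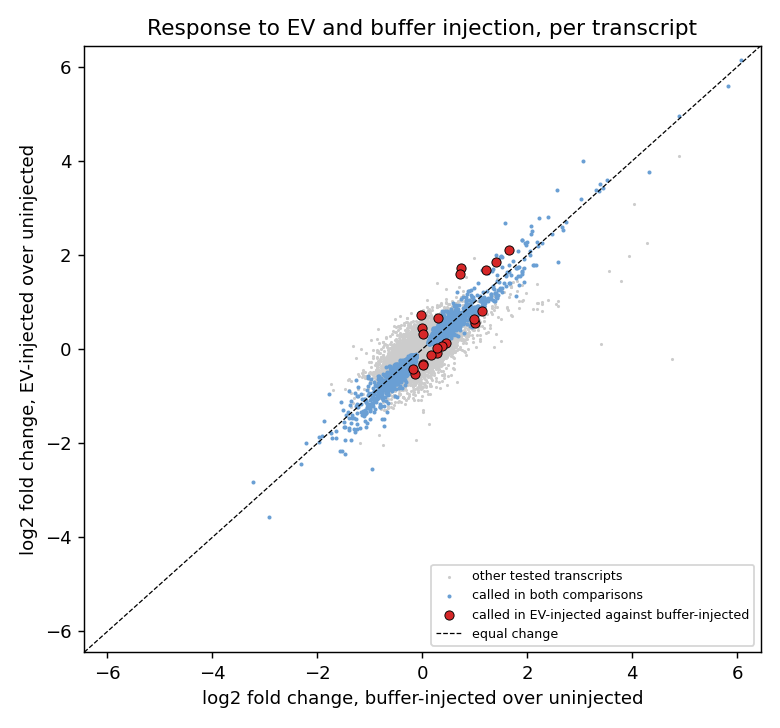
Log2 fold change of each of the 21149 tested transcripts in EV-injected over uninjected tails, against that in buffer-injected over uninjected tails; blue points are the 3730 called in both, red points the 21 called between EV-injected and buffer-injected tails, and the dashed line marks equal change. Called transcripts lie along the line, and red points lie close to it on either side.

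The comparison of EV-injected with buffer-injected tails addresses what EVs add to an injection. dd_Smed_v6_3606_0_1 was higher with EVs, at 57.1 ± 12.3 CPM against 28.3 ± 8.46 with buffer and 17.1 ± 1.69 without injection (SD, n = 4 each). Its log2 fold change over buffer was 1.00 ± 0.16 (SE, edgeR adjusted p = 0.0337). dd_Smed_v6_6474_0_1 was also higher, at 6.12 ± 1.66 against 3.32 ± 0.338 CPM, with 2.01 ± 0.237 CPM in uninjected tails. Its log2 fold change was 0.89 ± 0.16 (SE, edgeR adjusted p = 0.0422). dd_Smed_v6_5175_0_1 was lower with EVs, at 228 ± 16.7 against 309 ± 11.2 CPM, and both values lay above the 154 ± 15.4 CPM of uninjected tails. Its log2 fold change was −0.44 ± 0.06 (SE, edgeR adjusted p = 0.0233). dd_Smed_v6_2690_0_1 was lower as well, at 63.4 ± 6.91 against 82.6 ± 6.19 CPM, with 91.6 ± 5.31 CPM in uninjected tails. Its log2 fold change was −0.38 ± 0.07 (SE, edgeR adjusted p = 0.0448).

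**Figure D4:**
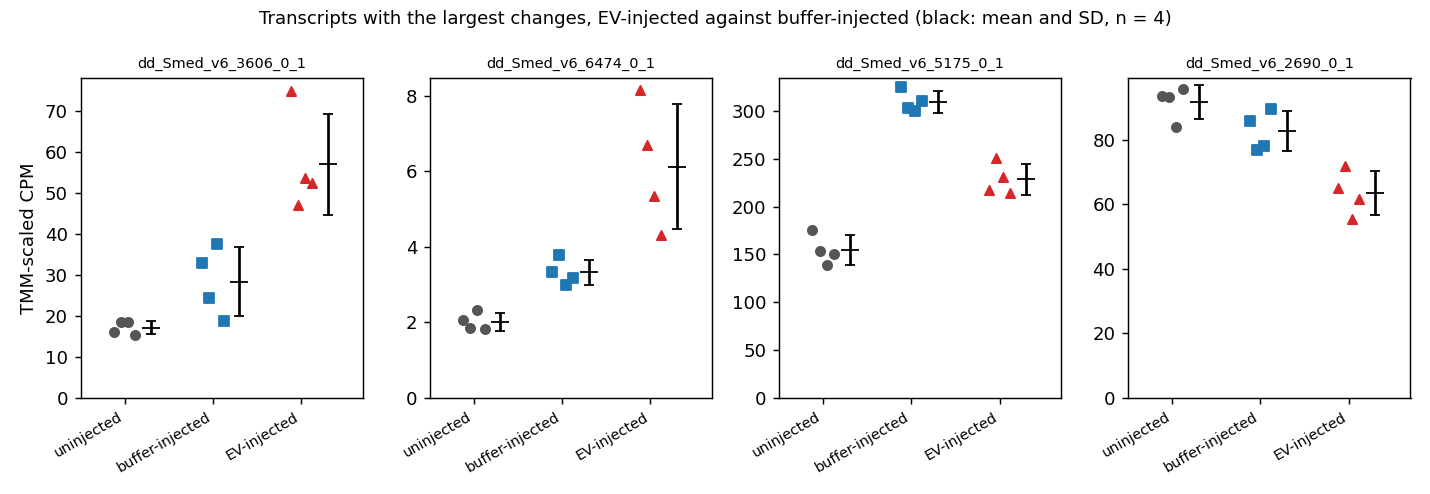
TMM-scaled CPM per library of the transcripts with the largest rises and falls in EV-injected against buffer-injected tails; points are libraries, and black marks are the mean and SD (n = 4) of each group. For all 4 transcripts the EV-injected libraries do not overlap the buffer-injected ones, which the rule that named them required.

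In all, 21 of 21149 transcripts were called with edgeR, 9 higher and 12 lower with EVs. The rises ran from 0.32 to 1.00 and the falls from −0.24 to −0.44 on the log2 scale. The EV-injected and buffer-injected libraries did not overlap for any of the 21. Over all tested transcripts 4.90% did not overlap, where chance gives 2.857%. At an unadjusted p under 0.05 there were 2129 transcripts, where 1057 would be expected without any difference. Other divisions of the 8 injected libraries into 4 and 4 gave up to 1868. The 95% interval of the fold change lay within 1.5-fold in either direction for 15563 transcripts, 73.6% of those tested, and within 2-fold for 19585, or 92.6%. The authors' deposited table calls 24 transcripts, 10 up and 14 down, and holds all 21. Of the 12 transcripts lower with EVs, 8 had risen after buffer injection, and of the 9 higher ones, 6 had. The calls that ran the same way against buffer and against uninjected tails were 13, 9 of them rises and 4 falls. Independent lists would share 1.2 and 1.4, but the EV-injected libraries enter both comparisons. Simulated data shared at most 1 without effects and at most 2 with the injection effect and no EV effect. They called at most 6 and 4 transcripts between EV-injected and buffer-injected tails, so 13 could not be reached. With the injection effect, the mean was 0.4 shared of 0.7 calls, so 13 of 21 is not shown to exceed chance sharing. Simulated libraries vary independently, while 26.9% of the real variance within groups lay along 1 axis, so these values do not exclude such variation. The axes of the buffer-injected and the EV-injected libraries taken alone correlated at only 0.0518 across transcripts. With the EV-injected libraries divided between the comparisons, 0 to 20 calls were shared.

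The edgeR count of 21 was 0 without EV-injected replicate 1 or EV-injected replicate 3 (1933 and 1798 at an unadjusted p under 0.05), 51 without EV-injected replicate 2 and 3 without EV-injected replicate 4. It was 8, 7 and 4 without buffer-injected replicates 1, 3 and 4, and 4 without uninjected replicate 2 or uninjected replicate 3. With all libraries, DESeq2 called 143 transcripts and edgeR on the 8 injected libraries alone called 6. Of 35 divisions of the injected libraries into 4 and 4, 2 gave as many calls, the real one included, and the other one called 37. Left out in turn, a library ended the call of dd_Smed_v6_3606_0_1 in 6 of 12 fits, of dd_Smed_v6_6474_0_1 in 9, of dd_Smed_v6_5175_0_1 in 3 and of dd_Smed_v6_2690_0_1 in 10, and no fold change turned its direction.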

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

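Values of 7 library measures and of the 8 named transcripts were checked for a library far from the other 3 of its group, 45 checks in all, of which chance alone would mark about 2.25. The check marked 1. Uninjected replicate 4 had counts for 26613 transcripts, against 27018 to 27096 in the other uninjected libraries, a gap that took 0.839 of the group's range. This library also had the smallest total, 19621187 counts.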

How the results depend on the processing

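Thinning, the axis covariate and the counts at 2-fold and 4-fold without a library were chosen after seeing the data. No list test or its alternatives could be run, since the files hold no gene names. Calls between EV-injected and buffer-injected tails (21) and those shared with EV-injected against uninjected tails (13) moved by over 1.5 times with DESeq2 (143 and 90), a robust fit (45 and 28), the replicate number as a block (39 and 28), only the 8 libraries compared (6 and 5), run 2 alone (8 and 6) and a minimum fold of 1.5 (3 and 3). With the axis covariate there were 44 calls between EV-injected and buffer-injected tails, where 10 simulated data sets without effects gave at most 2. Those simulated libraries vary independently and hold no such axis, so they do not test the 44 calls. The cause was not tested for DESeq2, the robust fit, the block or the covariate. Run 2 alone is shallower, 7055663 to 11613445 counts, and the fit to 8 libraries has fewer libraries to estimate the spread. With each library left out in turn, the counts were 0 to 51 and 0 to 39. DESeq2 size factors gave 21 calls, the same transcripts, and shifted no median log2 fold change by as much as 0.01.

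The replicate numbers did not pair the libraries. Correlations of deviations between libraries with the same number ran from −0.0204 to 0.139, and most libraries had their best partner under another number. The block gave 5483 calls in EV-injected and 4683 in buffer-injected against uninjected tails.

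Against uninjected tails, the total number of calls moved by over 1.5 times only with run 2 alone, 3537 with EVs and 2993 with buffer, and with a minimum fold of 1.5, 1006 and 932. Each library left out in turn gave 4554 to 5478 and 3773 to 4654 calls. Counts of large changes moved more. Over all settings, rises of 4-fold or more ran from 27 to 50 with EVs and 29 to 85 with buffer, and falls from 2 to 41 and 2 to 21. Without a filter scarce transcripts are tested too, and the cause was not tested for the other settings. The correlation of both responses, 0.826, was 0.879 with the filter of 1 CPM in 4 libraries, which removes scarce transcripts, 0.528 as the mean over divided controls, which takes away the shared controls and leaves each comparison fewer libraries, and 0.779 to 0.820 with a library left out. In 203 checks of 12 values of named transcripts, 172 kept their call, 31 lost it and 0 reversed. The losses were all between EV-injected and buffer-injected tails, where adjusted p ran up to 0.183. DESeq2 gave dd_Smed_v6_6474_0_1 no adjusted p. At the real depth and the spread estimated over all 12 libraries, simulated 1.5-fold changes between EV-injected and buffer-injected tails were recovered in 52% of cases. Thinning every library to 19621187 counts gave 22 calls against 21, but that is still the depth of the smallest library. Run 1 alone gave 21 calls and the shallower run 2 alone gave 8. Whether depth sets the limit was not settled.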

Other observations

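The values for single libraries, the test of damping and parts of the depth correlation were chosen after the results they concern were seen. A set of 21 transcripts, distinct from the 21 calls between EV-injected and buffer-injected tails, stood at least 4-fold above the mean of the other buffer-injected libraries in buffer-injected replicate 2. Their median there was 17.8 CPM and the highest value 84.4 CPM. They took 0.0617% of counts in that library, 0.0194% in buffer-injected replicate 3, 0.0171% in EV-injected replicate 3 and at most 0.00721% in any of the other 9 libraries. In EV-injected replicate 3, 90.5% of the set lay above the mean of the other EV-injected libraries. Of the set, 15 were called higher in buffer-injected than in uninjected tails, 14 of them at 4-fold or more, and 0 were called between EV-injected and buffer-injected tails. The large rises counted after buffer injection therefore include transcripts that rest on few libraries.

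The share of transcripts called rose with abundance. In EV-injected against uninjected tails it was 4.67% of 3556 transcripts with a mean log2 CPM under 0 and 53.7% of 633 with a mean over 8, and in buffer-injected against uninjected tails 4.75% and 45.8%. Of sets of identifiers that share their first number and hold at least 2 calls, 6 of 25 held calls in opposite directions in the former comparison and 3 of 17 in the latter.

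Other divisions of the libraries were fitted in the same way. For EV-injected against uninjected tails, 1 of 35 divisions of the 8 libraries gave as many calls as the real 5452, the real one itself, and the highest other gave 0. For buffer-injected against uninjected tails it was also 1 of 35, with 4659 calls against at most 1. By the bound set beforehand, chance division is argued against for these counts, and 1 of 35 is the least this check can give. Every other division mixes injected with uninjected libraries, which widens the spread within its groups. The gap in calls therefore does not measure how unlikely chance is. For EV-injected against buffer-injected tails, 2 of 35 divisions gave as many calls as the real 21, and the highest other gave 37, so chance division cannot be excluded for that count. That other division exchanged EV-injected replicate 2 with buffer-injected replicate 3, and 30 of the 35 divisions gave 0 calls. By the number at an unadjusted p under 0.05, which was not the planned measure, the real division was highest, 2129 against at most 1868. For the 13 calls shared with EV-injected against uninjected tails, 3 of 35 divisions gave as many, and the highest other gave 37, so chance division cannot be excluded there either.

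EV-injected tails had 793 more calls against uninjected tails than buffer-injected tails had. Library depth is argued against, since thinning every library to 19621187 counts left a difference of 821. A single buffer-injected library is argued against as the whole explanation. The highest buffer count with such a library left out was 4429, below the lowest EV count of 4560 with an EV-injected library left out. These counts come from different fits and lie close together, so such a library may still account for part of the difference. A single EV-injected library stays open, since the difference was 48 to 429 with such a library left out, though the group then also has fewer libraries. Chance division stays open: 4 of 70 ordered divisions gave a difference as large, and the highest other was 1042. An effect of EVs, which the design names, may add to the response and was not separated from chance here.

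Most of the transcripts lower with EVs than with buffer, 8 of 12, had risen after buffer injection. A general damping of the injection response by EVs is argued against. Over the 4659 transcripts called after buffer injection, the slope of the EV-minus-buffer difference on the buffer response, each taken from other buffer-injected libraries, ran from −0.0790 to 0.0920, above the bound of −0.2. The buffer-injected libraries enter both comparisons, which could by itself yield such transcripts. Simulated data with the injection effect but no EV effect gave at most 2 in 20 draws. The bound set beforehand would exclude that explanation. Those draws called at most 4 transcripts between EV-injected and buffer-injected tails, so 8 could not be reached. On average 0.2 of 0.7 calls were of this kind. Simulated libraries also vary independently, while real libraries vary along an axis within groups. For both reasons it was wrong to rely on that bound. EV-injected against uninjected tails use no buffer-injected library, and there 3 of the 8 rose and 5 were not called, so shared libraries and a damped response of these transcripts alone cannot be told apart.

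Within groups, libraries varied along an axis that held 26.9% of the within-group variance, with buffer-injected replicate 2 at its end with a score of 0.573. Transcript length, a sign of RNA integrity, is argued against, since it explained 0.128% of the variance of the weights. Depth is argued against as well. Scores of the 12 libraries before and after thinning correlated at Pearson r = 0.9996 and Spearman rho = 0.993, and at r = 0.999 without the 2 farthest libraries. Depth within groups and the score correlated at Pearson r = −0.0431 (permutation p = 0.929) and Spearman rho = −0.119 (permutation p = 0.784), and at r = −0.280 without the 2 libraries farthest in depth. Libraries that differ in the strength of the injection response remain a possible explanation. The weights among buffer-injected libraries correlated at 0.262 across 15065 transcripts with the EV-injected against uninjected fold changes, between the bounds of 0.1 and 0.3 set beforehand. They correlated at 0.306 with the weights among uninjected libraries, which had no injection. The weights among EV-injected libraries correlated at 0.0518 with those among buffer-injected and at 0.131 with those among uninjected libraries. With the buffer-injected against uninjected fold changes they correlated at 0.171. An axis common to all groups was therefore not shown.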
